A study of Mus musculus with 9 samples.

How the data were processed

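Total RNA from cerebral cortex of 9 mouse embryos at stage E13.5 was hybridised to Affymetrix Mouse Exon arrays, 1 array per embryo sample, with 3 samples in each of the control, Sfpq+/- and Sfpq-/- groups. Groups were taken from the titles and genotype fields; the extraction notes name Sfpq+/- in both places after control and Sfpq-/- nowhere. The labels give no litter, slide or date. The labels do not state that samples of a group came from separate litters, so p-values measure the spread between these samples.

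The values the authors deposited are log2 signals per probe set, made with Affymetrix Expression Console 1.2.0.20 per the submitters' processing notes. The series' design text also names the Affymetrix Exon Array Computational Tool. The background correction, normalization and summary method are not given in the sources used here. The unit was taken from the values, which run from 0 to about 15 with nearly equal quartiles on all 9 arrays, and no further normalization was applied. A total of 20744 probe sets are listed at 0 on all arrays. No 2 arrays were identical.

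Probe sets were named from the platform annotation that was provided. Of 1256831 probe sets, 318760 (25.4%) had 1 gene symbol, 6684 had several and 931387 had none there; the last are unnamed here, not without a gene. Symbols were updated through RefSeq synonyms where the synonym was unique: 18006 symbols were current, 3993 were updated, 63 were kept as given, and 234 were not updated because symbols would have merged. Odz2 was kept as given. Probe sets with several symbols were used in no gene.

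Probe sets were kept where their mean over all 9 arrays was above the median of all probe set means (5.64), which left 628415. The level of a gene was the mean of its kept probe sets, for genes with at least 3, which gave 16854 genes from 248590 probe sets. Different probe sets of a gene can disagree, as the exon usage results show. All 9 arrays entered 1 linear model per gene with 3 group means and no covariates, in limma 3.58.1 (lmFit and eBayes, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Probe sets were tested in the same way. Exon usage was tested with diffSplice (F test). Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The 22 lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. By that rule the text names, per comparison, the 10 higher and 10 lower genes with the largest log2 change among those that passed and whose arrays did not overlap, or, where none passed, the 3 with the smallest unadjusted p. In each list it names up to 4 members with the smallest adjusted p, and all members that passed in lists that camera called if at most 10 did. For exon usage it names the 10 genes with the smallest p. Sfpq is always named, Eomes was added outside the rule, and names that are clone numbers are left out. By chance, 10% of genes have arrays that do not overlap between 3 and 3.

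Gene spans were taken from a RefSeq gene table of assembly GRCm38.p6, matched by symbol alone and used only to place genes in span classes. A span was found for 16704 of the 16854 genes (99.1%). The build behind the array annotation is not given in the sources used here, so no coordinates are reported. Positions of probe sets within genes were not used here, and the planned comparison of positions within long genes was not run.

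The tests of genes, gene lists, exon usage, probe sets and gene length were run on simulated data drawn from the measured means and residual spreads. With 200 genes changed in Sfpq-/- against control among 16854, 61.2% of genes changed by 0.5, 98.5% of those changed by 1 and 100% of those changed by 2 on the log2 scale were found, with 13 false calls. For Sfpq+/- against control, where no gene was changed, there were 0 calls. A list of 44 genes shifted in Sfpq-/- against control was called among 16854 genes, and 0 of 40 random lists were. Among 628415 probe sets, 45 of 100 changed by 2 and 0 of 100 changed by 1 were found, with 1 false call, so the probe set counts miss many changes of these sizes. In 1 simulation each, camera called a shift of -0.1 in genes of at least 100 kb and did not call them without a shift. Genes were drawn independently in the simulations of lists and gene length. These therefore do not measure camera's false calls where the genes of a list vary together. The probe set and gene length simulations were added after seeing the data. The diffSplice tests failed this check: for Sfpq-/- against control on 3000 genes, with no change planted and the measured variance of each probe set, the F test called 27 genes and the Simes test 210. With equal variance within a gene both called 0. With 200 genes changed, 31% of the F test's calls and 60.2% of the Simes calls were false. A test on each probe set's deviation from its gene's mean, with its own moderated variance and a Simes combination per gene, was therefore added. It called 0 genes with no change planted and had 5.3% false calls with 200 genes changed, and it found 49 of 100 genes whose probe set changed by 1 and 94 of 100 changed by 2. These exon usage simulations changed single probe sets and no whole gene. They do not measure false calls that arise where the level of a gene changes. The F test remains the planned result and is printed with its share of false calls in simulation.

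The alternatives were quantile normalization, centring of arrays, other limits on dim probe sets, the median of probe sets, genes with at least 1 kept probe set, a trended and robust prior, array weights, fits of only the groups compared, the replicate number as a block, leaving out each array, span limits of 50 and 200 kb, and Simes adjustment. Chosen after seeing the data were leaving out control 3 and Sfpq-/- 3 together, leaving out genes on X and Y, gene-by-gene array weights and the exon usage test with own variances.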

Results

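Exon-level expression was measured on whole-transcript exon arrays in cerebral cortex dissected from mouse embryos at stage E13.5. The 9 arrays came from 3 groups of 3 embryos each: controls labelled wild type, embryos labelled Sfpq+/-, and embryos labelled Sfpq-/-. Sfpq encodes a nuclear RNA-binding protein of the DBHS family, which takes part in transcription, RNA processing and paraspeckle assembly. Per the labels there was 1 array per sample and no technical replicate. The 9 arrays held 1256831 probe sets each, with array medians between 5.648 and 5.697 on the log2 scale. The number of arrays, 3 per group, limits the precision, and the median standard error of a difference between group means was 0.096 on the log2 scale per gene. Gene levels were tested for 16854 genes with limma and Benjamini-Hochberg adjustment.

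Sfpq signal was examined first, as a check of the labels. Of 23 probe sets for Sfpq, 12 had a control mean above 10, and their mean signal was 12.09 ± 0.03 (SD, n = 3) in controls, 11.96 ± 0.11 (SD, n = 3) in Sfpq+/- and 10.13 ± 0.17 (SD, n = 3) in Sfpq-/- cortex. The mean of these probe sets was 3.90-fold lower in Sfpq-/- than in control cortex (log2 change -1.97, SE 0.10, limma adjusted p = 1.03e-06), and each Sfpq-/- array lay below each control array. Of the 12 probe sets, 11 fell in Sfpq-/-, with a median log2 change of -2.08. In Sfpq+/- the same mean differed by -0.13 (SE 0.10, limma adjusted p = 0.886), less than could be told from the spread between arrays. The 95% interval of that difference ran from -0.34 to 0.08, above the log2 change of -1 that a loss of 1 of 2 copies would give at equal output per copy. Sfpq signal thus does not set the Sfpq+/- arrays apart from controls and does not check that label. The average of all kept Sfpq probe sets, which includes dim ones, fell by 1.15 in Sfpq-/- (limma adjusted p = 0.000787) and differed by 0.12 in Sfpq+/- (limma adjusted p = 0.9), a sign opposite to that of the bright probe sets. The titles and genotype fields name all 3 groups, but the extraction notes name Sfpq+/- in the place where Sfpq-/- would be expected. The labels do not say which exons were deleted, so a probe set outside the deleted part checks nothing.

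**Figure D1:**
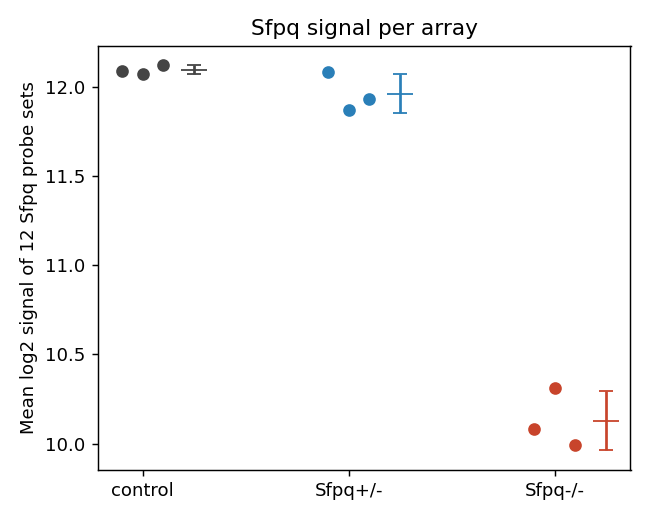
Mean log2 signal of the 12 Sfpq probe sets with a control mean above 10 on each array (points) for control, Sfpq+/- and Sfpq-/- cortex, with the group mean and SD (n = 3) beside the points. The vertical axis does not start at 0. The 3 Sfpq-/- arrays lie between 9.99 and 10.31 and the 3 control arrays between 12.07 and 12.12.

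In Sfpq-/- against control cortex the netrin receptor Dcc fell 5.16-fold (log2 change -2.37, SE 0.12, adjusted p = 1.17e-06), and Nkain2 fell by the same log2 amount (-2.37, SE 0.08, adjusted p = 2.74e-07). The netrin receptor family member Unc5d (-2.21), the kainate receptor subunit gene Grik2 (-2.19), the transcription factor Npas3 (-2.27) and the diacylglycerol kinase Dgkb (-2.21) also fell. Sytl5 (-2.13), Vit (-2.09), Frmd5 (-2.08) and Aim2 (-2.05) completed the 10 lower genes with the largest change. The Sfpq-/- means of Sytl5 (5.40), Vit (5.87) and Dgkb (5.90) lay near the limit for dim probe sets (5.64), so their falls may be underestimated and their ranks are not exact. Across the alternatives the log2 change ran from -2.433 to -1.784 for Sytl5, from -2.216 to -1.817 for Vit and from -2.379 to -1.857 for Dgkb. The bHLH transcription factor Olig3 rose 8.43-fold (log2 change 3.08, SE 0.24, adjusted p = 1.2e-05), from 6.23 ± 0.13 to 9.31 ± 0.51 (SD, n = 3). Tyrosine hydroxylase, Th, the rate-limiting enzyme of catecholamine synthesis, rose by 2.51 and the fatty acid elongase Elovl7 by 2.56. Mab21l2 (2.35), the calcium-binding protein gene Calb1 (2.12), the zinc finger transcription factor Fezf1 (2.07), Them5 (1.99), the retinoic acid-binding protein gene Crabp2 (1.78), the Delta-like gene Dlk1 (1.59) and Rgs13 (1.59) rose as well. Each of these 20 genes passed limma's test with adjusted p of 0.00272 or less and had no overlap between the 3 control and 3 Sfpq-/- arrays. In all, 1008 genes were higher and 1032 lower, of which 53 and 151 changed by over 2-fold. The balance of the directions depended on single arrays: 1477 were higher and 976 lower without Sfpq-/- replicate 3, 769 and 1168 without Sfpq-/- replicate 2, and 543 and 768 without Sfpq-/- replicate 1. Without control replicate 2 the total was 1343 genes (574 higher and 769 lower), and without Sfpq-/- replicate 1 it was 1311, in place of 2040. With array weights estimated gene by gene, an alternative chosen after seeing the data, it was 4609 (2755 higher and 1854 lower).

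Gene span, the length of a gene from its first to its last annotated base, set apart the genes that fell. Among 205 genes spanning at least 500 kb, 119 fell and 1 rose in Sfpq-/-, and their median log2 change was -0.45 (quartiles -0.82 and -0.10). Among 713 genes of 200 to 500 kb, 272 fell and 32 rose (median -0.18). The median was 0.00 for 1336 genes of 100 to 200 kb, and it lay between 0.03 and 0.04 in each class below 100 kb. Genes of at least 100 kb made up 58.9% of the lower genes (608 of 1032) and 13.2% of the higher genes (133 of 1008), against 2254 of the 16704 genes with a span. Their median lay 0.103 below that of shorter genes (-0.103; camera p = 3.92e-14, and p = 0.0398 with an estimated correlation). Each array was also measured against the mean of the 3 control arrays. The difference between long and short genes was then -0.133 ± 0.022 (SD, n = 3) in Sfpq-/- and -0.002 ± 0.017 (SD, n = 3) in control arrays. A two-sided permutation of these values gave p = 0.1, the smallest that 3 against 3 arrays can give. The controls form that mean, so their values lie near 0 by construction. The mean was not recomputed in the permutation, so its p is approximate. The position of probe sets within long genes was not analysed here.

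**Figure D2:**
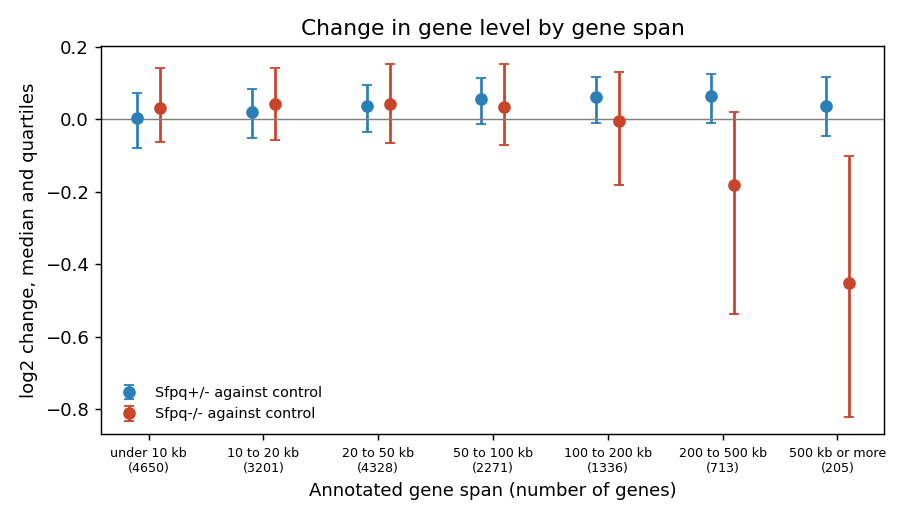
Change in gene level against annotated gene span, with the number of genes in each class under the horizontal axis. Points are median log2 changes and bars run between the quartiles across genes, for Sfpq+/- (blue) and Sfpq-/- (red) against control. The Sfpq-/- median is -0.18 for genes of 200 to 500 kb and -0.45 for genes of 500 kb or more.

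Of 44 measured members of the list of very long neural and adhesion genes, 32 fell in Sfpq-/- and none rose (camera adjusted p = 1.03e-36, and adjusted p = 0.00682 with an estimated correlation). Adjusted over the list alone, 40 fell. Examples are Dcc, the adhesion molecule gene Cadm2 (-1.64), the alpha-catenin gene Ctnna2 (-1.54) and the reelin pathway adaptor Dab1 (-1.35). In the axon guidance list 17 of 23 members fell and 1 rose (19 and 1 adjusted over the list alone; camera adjusted p = 4.66e-16, but adjusted p = 0.153 with an estimated correlation). Unc5d, Dcc, the ephrin receptor Epha5 (-1.59) and Slit1 (-1.07) led this list. Dcc, Robo1 and Robo2 stand in both lists. Unc5d and Dcc span 573 and 1097.6 kb. Short members of the axon guidance list were not tested apart, so its fall was not told apart from that of long genes.

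Markers of neuronal stages moved in part. In the intermediate progenitor list Neurod4 (-1.11), the proneural factor Neurog2 (-0.92) and Insm1 (-0.37) fell and Dll3 (0.70) rose, of 14 measured (2 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.212). Eomes, named outside the naming rule after its values were seen because it was the only other member to pass, differed by -0.23 (adjusted p = 0.0489), and its call ended in 5 of the 6 fits that left out 1 array. Among 21 projection neuron genes, Myt1l (-1.01), the synaptotagmin gene Syt1 (-0.77), Sox5 (-0.59), the subcortical projection neuron factor Fezf2 (-0.49) and Neurod6 (-0.41) fell, while Neurod1 (0.36) rose (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0213, but adjusted p = 0.731 with an estimated correlation). That call ended without control replicate 1 (adjusted p = 0.0582), without Sfpq-/- replicate 2 (adjusted p = 0.104) and with the median of probe sets as gene level (adjusted p = 0.257). The 5 projection neuron genes spanning at least 100 kb had a median change of -0.586 and the 16 shorter ones -0.051. The fall of this list was therefore not told apart from that of long genes. Of 19 radial glia genes Pou3f2 (-0.51), Lhx2 (-0.34) and Cdh2 (-0.41) fell, 3 also when adjusted over the list alone (camera adjusted p = 0.064), and Hes5 differed by -0.27 (adjusted p = 0.0849). Of 11 Cajal-Retzius genes 6 rose, also when adjusted over the list alone: Lhx5 (1.02), Ebf2 (0.73), the calretinin gene Calb2 (0.69), Lhx1 (0.48), Nhlh2 (0.41) and Ebf3 (0.34) (camera adjusted p = 0.0411, but adjusted p = 0.611 with an estimated correlation). Without Sfpq-/- replicate 2 and without Sfpq-/- replicate 3 this camera call ended (adjusted p = 0.0532 and 0.137), as it did with the median of probe sets (adjusted p = 0.0765). The other 5 Cajal-Retzius genes, Reln and Trp73 among them, did not pass. A difference in the tissue dissected, left open below for other genes that rose, was not tested for this list. Of the 6 fits that left out 1 array, the calls of single genes ended in 4 for Neurod1, 4 for Cdh2, 2 for Ebf3 and 1 for Lhx1.

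In the G2 and M phase list Aurkb (-0.39), Plk1 (-0.35), Aurka (-0.46), Ccnb2 (-0.32) and Kif20a (-0.37) fell, 5 of 19 members (6 adjusted over the list alone; camera adjusted p = 1.44e-06, but adjusted p = 0.611 with an estimated correlation). The mean change of the G2 and M phase list was -0.282, and it was -0.153 without Sfpq-/- replicate 3 and -0.414 without Sfpq-/- replicate 2, with the camera call kept in both. The calls of Kif20a, Ccnb2 and Aurka ended in 5, 3 and 2 of the 6 fits that left out 1 array. None of 16 S phase genes passed by itself, on all genes or over the list alone (camera adjusted p = 0.0411, but adjusted p = 0.813 with an estimated correlation). Pcna differed by -0.27 (adjusted p = 0.114), Gins2 by -0.21 (adjusted p = 0.106), Cdc6 by -0.22 (adjusted p = 0.203) and Uhrf1 by -0.22 (adjusted p = 0.209). The S phase call ended without control replicate 1 (adjusted p = 0.14), without control replicate 2 (adjusted p = 0.0918) and without Sfpq-/- replicate 3 (adjusted p = 0.354).

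Of 26 p53 target genes 9 rose and none fell in Sfpq-/- (10 higher adjusted over the list alone; camera adjusted p = 0.000209, but adjusted p = 0.203 with an estimated correlation). They were Eda2r (1.37), Ccng1 (0.84), Sesn2 (0.68), Phlda3 (0.56), the cell cycle inhibitor gene Cdkn1a (0.52), Ptpn14 (0.39), Tnfrsf10b (0.37), Sesn1 (0.32) and Aen (0.27). Sesn2 was also the 1 member to rise among 22 genes of the integrated stress and unfolded protein responses, on all genes and over the list alone (camera adjusted p = 0.138). In that list Asns (0.25, adjusted p = 0.0721), Chac1 (0.31, adjusted p = 0.082) and Phgdh (0.35, adjusted p = 0.105) did not pass. Of 17 clock genes 5 rose, also when adjusted over the list alone: Dbp (0.59), Nr1d1 (0.59), Nr1d2 (0.50), Bhlhe41 (0.50) and Per1 (0.49) (camera adjusted p = 0.00119, but adjusted p = 0.202 with an estimated correlation). Among 21 DBHS, paraspeckle and related RNA-binding protein genes the Sfpq paralog Pspc1 rose by 1.09 (adjusted p = 0.000337) and no other member passed, over the list alone either (camera adjusted p = 0.33). Matr3 differed by 0.29 (adjusted p = 0.0885), Rbm14 by 0.19 (adjusted p = 0.176) and Nova1 by -0.25 (adjusted p = 0.268). In the DNA repair list Trp53bp1 (0.36) rose and Rad51c (-0.42) fell among 21, none over the list alone, while Xrcc4 (-0.16, adjusted p = 0.249) and Lig3 (0.17, adjusted p = 0.274) did not pass (camera adjusted p = 0.776). Of 16 immediate-early genes Ccn1 (-0.47) and Jun (-0.30) fell, 3 lower and 1 higher over the list alone (camera adjusted p = 0.827), and Arc (-0.22, adjusted p = 0.0652) and Klf4 (0.34, adjusted p = 0.0739) did not pass. Of the 6 fits that left out 1 array, the call ended in 5 for Aen, 5 for Rad51c, 4 for Trp53bp1, 4 for Jun, 3 for Cdkn1a, 3 for Tnfrsf10b, 2 for Sesn1, 2 for Nr1d2, 1 for Phlda3 and 1 for Ptpn14. The immediate-early list's median (0.029) and mean (0.01) had the opposite sign to camera's direction.

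Marker genes of other cells in the tissue were measured beside these. Of 16 microglia and macrophage genes 7 rose: Cd68 (0.51), Tyrobp (0.36), C1qc (0.35), Trem2 (0.34), Cx3cr1 (0.31), C1qb (0.30) and P2ry12 (0.28) (9 adjusted over the list alone; camera adjusted p = 0.000169, but adjusted p = 0.202 with an estimated correlation). Of the 6 fits that left out 1 array, the call ended in 6 for Cx3cr1, 5 for each of C1qb, C1qc, Trem2 and P2ry12, 3 for Tyrobp and none for Cd68. In the ganglionic eminence and interneuron list Gad1 (0.98) and Ebf1 (0.62) rose and Sst (-0.69) fell among 16 (3 higher and 1 lower over the list alone; camera adjusted p = 0.845), and Sp8 differed by 0.43 (adjusted p = 0.0726). Rspo3 (0.32) rose among 15 dorsal midline and choroid plexus genes (1 over the list alone; camera adjusted p = 0.845) and Rgs5 (0.30) among 17 endothelial and pericyte genes (1 over the list alone; camera adjusted p = 0.0536). The calls of Rspo3, Rgs5 and Sst ended in 5, 5 and 4 of these fits. None of 16 meningeal and mesenchymal genes (camera adjusted p = 0.147) and none of 12 erythroid genes (camera adjusted p = 0.138) passed, over the lists alone either. Of 3 measured histone and small RNA genes none passed (1 higher over the list alone; camera adjusted p = 0.827). Embryo sex was not matched between groups. Xist, the RNA made by the inactive X chromosome, was between 11.48 and 11.79 on control 1, control 2 and Sfpq-/- 1 and between 4.90 and 5.87 on the other arrays. The Y-linked gene Kdm5d was between 8.83 and 9.38 on those other arrays. None of the 3 sex-linked genes passed in Sfpq-/- (camera adjusted p = 0.866). Without genes on the X and Y chromosomes, an alternative chosen after seeing the data, 1960 genes were called. Fry called the lists of very long genes (fry adjusted p = 6.08e-06), axon guidance (0.000276), clock genes (0.00262) and microglia (0.00334) in Sfpq-/-. It also called the p53 target (0.00442) and Cajal-Retzius lists (0.0106), and the stress response list (0.0358), which camera did not call. Camera's projection neuron, G2 and M phase and S phase calls did not pass fry (adjusted p = 0.107, 0.109 and 0.45).

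**Figure D3:**
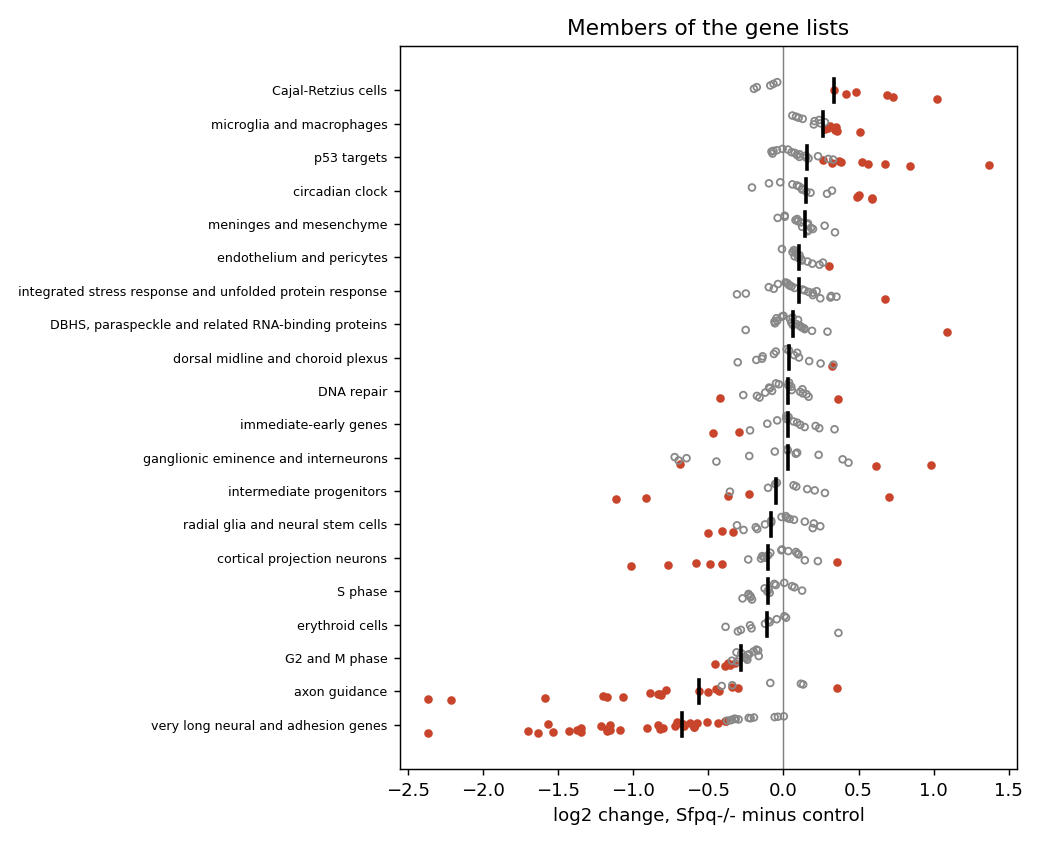
Log2 change between Sfpq-/- and control cortex for each measured member of 20 gene lists (lists with over 3 measured members), one row per list. Filled red points passed the test at an adjusted p under 0.05, open grey points did not, and black bars are list medians; the very long neural and adhesion genes have a median of -0.67.

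Sfpq+/- against control cortex gave no gene past the threshold in limma's test, and 715 of 16854 genes at an unadjusted p under 0.05 where 843 are expected by chance. The smallest unadjusted p values, none of which passed, were those of Tcte2 (0.44, SE 0.08, adjusted p = 0.886), Unc79 (0.32) and Gpr52 (0.36) among higher genes and of Kcnip1 (-0.39), Lemd1 (-0.52) and Nkain2 (-0.43, SE 0.08) among lower genes. Camera called the projection neuron list (median 0.16, adjusted p = 4.03e-07) and the axon guidance list (median 0.11, adjusted p = 0.0226) as higher. But no member of either list passed, and with an estimated correlation adjusted p = 0.992 for both. Fry called neither list (fry adjusted p = 0.548 and 0.768). The axon guidance call ended without control replicate 1 (adjusted p = 0.0725), without control replicate 2 (adjusted p = 0.202) and without Sfpq+/- replicate 1 (adjusted p = 0.235). Embryo sex differed from the controls here, since all 3 Sfpq+/- arrays were low in Xist and 1 of 3 controls was. Xist differed by -4.26, Eif2s3y by 3.08 and Kdm5d by 3.08 (adjusted p = 0.886 for each; 2 higher and 1 lower over the list alone; camera adjusted p = 0.525). Without genes on X and Y, an alternative chosen after seeing the data, 0 genes were called, with 696 at an unadjusted p under 0.05. Genes of at least 100 kb lay 0.035 above shorter genes (camera p = 0.00143, but p = 0.313 with an estimated correlation). With each array measured against the control mean as above, the difference was 0.031 ± 0.029 (SD, n = 3). In controls, near 0 by construction, it was -0.002 ± 0.017 (two-sided permutation p = 0.3, approximate as above). With array weights that did not converge, 868 genes passed, and with gene-by-gene weights none did, with 2656 at an unadjusted p under 0.05.

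Sfpq-/- was also compared with Sfpq+/- cortex directly, and 772 genes were higher and 1222 lower. The higher count depended on single arrays: 469 were higher and 937 lower without Sfpq+/- replicate 1, and 479 and 918 without Sfpq-/- replicate 1. With alternatives chosen after seeing the data, 1087 were higher and 1106 lower without control 3 and Sfpq-/- 3, and 1730 and 1905 with gene-by-gene weights. Olig3 (2.91), Th (2.83), Mab21l2 (2.71), Elovl7 (2.45), Crabp2 (2.02), Fezf1 (1.88), Dlk1 (1.87), Calb1 (1.86), Pdlim3 (1.71) and Samd3 (1.68) were higher. The transcription factor Tfap2d (-2.49), Unc5d (-2.32), Npas3 (-2.30), Dcc (-2.30) and Grik2 (-2.24) were lower. So were Sytl5 (-2.15), the semaphorin gene Sema5a (-2.15), Dgkb (-2.12), Frmd5 (-2.04) and Aff2 (-2.02). The falls of Tfap2d (Sfpq-/- mean 5.82), Sytl5 and Dgkb may again be underestimated. Across genes, which are not independent replicates, the log2 changes of Sfpq+/- and Sfpq-/- against the shared controls correlated with r = 0.187. Simulated unchanged groups gave r = 0.497 against shared controls. That simulation held no changed gene in Sfpq-/-, and the real changes there can lower r whatever Sfpq+/- does. The gap between the 2 values of r therefore shows nothing about Sfpq+/-. Leaving out single arrays moved r from 0.061 (without Sfpq-/- replicate 2) to 0.31 (without control replicate 1). The covariance of the changes was 0.00659 beside a simulated 0.00737. Of the 2040 genes changed in Sfpq-/-, 54.9% differed in the same direction on the arrays labelled Sfpq+/-: 76.9% of the higher genes lay above 0 there and 33.3% of the lower genes below 0. The median Sfpq+/- change was 0.073 for the higher genes, 0.043 for the lower genes and 0.03 for all genes, so both groups leaned upward. Over all genes 62.4% had the same sign, beside 66.7% in the simulation of unchanged groups, a share that the changes in Sfpq-/- can lower likewise. No gene was called in both comparisons, which was fixed beforehand because none was called in Sfpq+/- against control. The controls were too few to split, and part of any likeness may come from the shared controls.

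At the level of single probe sets, 3528 were higher and 7479 lower in Sfpq-/- than in control cortex among 628415 tested, while none passed in Sfpq+/- (28244 at an unadjusted p under 0.05). Without Sfpq-/- replicate 1, control replicate 2 or control replicate 3 the Sfpq-/- count of 11007 was 5594, 5701 and 6546. Differential exon usage asked whether the probe sets of a gene changed unequally. In Sfpq-/- the text names, for the 10 genes with the smallest p, the probe set with the largest usage difference. In Nxn, the nucleoredoxin gene, 1 probe set rose from 7.75 ± 0.31 to 11.41 ± 0.27 (SD, n = 3) while the gene average differed by -0.28. In the reticulon gene Rtn3 1 probe set rose from 6.76 ± 0.31 to 10.69 ± 0.09, against 0.61 for the gene. In Aff3 it rose from 7.74 ± 0.55 to 10.25 ± 0.31 and in Dock1 from 6.08 ± 0.47 to 8.05 ± 0.29, while the genes differed by -0.93 and -0.47. In Msi2 it went from 7.45 ± 0.41 to 8.61 ± 0.30 (gene -0.79). In Sox5 it went from 6.07 ± 1.5 to 7.78 ± 0.76 (gene -0.59), a difference near the spread of the control arrays. In Fat3, Odz2, Ankrd6 and Ctnnd2 it differed by 0.49, 0.42, 0.28 and 0.14 with control SDs of 0.29, 0.30, 0.28 and 0.14, while the gene averages differed by -1.14, -1.30, -1.37 and -1.34.

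The planned F test of limma's diffSplice called 1282 genes in Sfpq-/- and 2 in Sfpq+/- (542 at an unadjusted p under 0.05). The test takes the probe sets of a gene to be equally variable, and in simulated data of this comparison with unequal variances 31% of its calls were false. With each probe set's own variance, a test chosen after seeing the data, 582 genes were called in Sfpq-/- and 0 in Sfpq+/- (612 at an unadjusted p under 0.05). Of the 582 genes, 540 were also called by the F test, and all 10 genes named here were among those called, with adjusted p between 0.000232 and 0.0106. Of the 582, 62.5% spanned at least 100 kb and 67% were also changed in gene level. The simulations changed no whole gene, so their false calls do not cover genes that changed in level. In such genes a dim probe set can move less than its gene, and this was not tested apart. The F test's count rose to 3496 without Sfpq-/- replicate 3, and in Sfpq+/- to 80 without control replicate 1.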

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

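The comparison of Sfpq-/- with Sfpq+/- was planned; the tests of explanations were chosen after the patterns were seen, with their bounds set before their own values were except where stated, and the other splits of the arrays after. The effect of genotype differed between Sfpq-/- and Sfpq+/- cortex when the difference itself was tested: 1994 genes passed limma's test of Sfpq-/- against Sfpq+/-, and the median of genes of at least 100 kb lay 0.143 lower than that of shorter genes in the same comparison (-0.143; camera p = 3.17e-18, and p = 0.0237 with an estimated correlation). Groups of 3 are too small for a search for single outlying samples.

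Long genes were lower in Sfpq-/- cortex. Unequal signal level or probe set number of long genes does not account for this: against short genes matched on both, the median difference was -0.115 (95% bootstrap interval -0.129 to -0.10), beside -0.103 unmatched. All intervals in this section resample genes as if independent. They do not measure the spread between embryos and may be too narrow. A lower share of neurons in the tissue is argued against as the whole cause only for genes of at least 500 kb. Their median was -0.451, while the 16 projection neuron markers spanning under 100 kb had a median change of -0.051 (interval -0.13 to 0.083). The 5 projection neuron markers of at least 100 kb had -0.586. All genes of at least 100 kb had a median of -0.066. That lies within the interval of the 16 short markers, so for this wider class the markers cannot decide. Differences in level or distribution that remained between arrays were also taken out. The difference between long and short genes was -0.102 after quantile normalization, which moved the number of genes called to 2210, and -0.103 after centring. Camera called both, and the bound, set after the values were seen, was met. The deposited arrays already had nearly equal quartiles, so these steps could move little and no conclusion is drawn from them. The background correction, normalization and summary method of the authors were not tested and stay open. A direct effect of genotype on long genes was not tested further.

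Olig3, Fezf1 and Mab21l2, 3 of the 10 higher genes with the largest change, rose in Sfpq-/- cortex. More midbrain or hindbrain tissue and more diencephalic tissue in the dissected samples both stay open. Of 16 measured midbrain and hindbrain markers 1 passed upward (Foxa1, 0.52, control mean 7.08, a call that ended in 4 of the 6 fits that left out 1 array), with an interval of the median of -0.028 to 0.094, which met the bound set beforehand against this explanation. That bound was wrong, because the median control level of these markers was 7.53 beside 8.35 for all genes, and because the list left out genes already seen to rise; the limit on dim markers was added after the values were seen. Of 19 measured diencephalic markers, with a median control level of 7.56, 2 passed upward (Sox14, 0.80, and Lhx9, 0.54), none passed downward and the interval of the median ran from -0.035 to 0.336. Both marker lists were written after the named genes were seen. Dbx1, Barhl2 and Tcf7l2, which also rose and are given under the other observations, are on neither list.

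Control 3 and Sfpq-/- 3 stood at one end of the second principal component (-19.3 and -17.4, with 22.3% of the variance), and across genes their deviations from the group means correlated with r = 0.574. Sfpq+/- 3 deviated with both to a lesser degree (r = 0.31 with control 3 and 0.30 with Sfpq-/- 3). A difference between arrays that depends on the mean level of a gene is argued against. After a smooth function of that level was taken out of each array, r was 0.492 (interval across genes 0.468 to 0.515). A signal-dependent difference at the level of probe sets, which a gene average mixes, was not tested and stays open. Control 3 and Sfpq-/- 3 had the highest first quartiles of probe set signal (4.02 and 4.012) and the lowest 99th percentiles (12.238 and 12.242). Embryo sex acting through genes on X and Y is argued against by r = 0.566 without these genes; the explanation was narrowed to X and Y after the value was seen, and effects of sex on other genes stay open. Had sex been the cause, Sfpq-/- 2, as low in Xist, was expected beforehand to deviate with control 3, and it did not (r = -0.34 over all genes); but it is 1 array, and its deviations are measured from a mean that holds Sfpq-/- 3, so this value alone excludes nothing. Differences in dissection or handling were not tested.

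Other splits of the same 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. For genes the real split gave 2040 in Sfpq-/- against control and the highest other split 3, and 1 of the 10 splits was as large as the real one. For Sfpq-/- against Sfpq+/- these were 1994 and 0, again with 1 of 10 as large, and for Sfpq+/- against control 0 and 0, with 10 of 10 as large. For probe sets they were 11007 and 103 in Sfpq-/- (1 of 10) and 0 and 0 in Sfpq+/- (10 of 10). For exon usage by the F test the real split of Sfpq-/- and control gave 1282 genes and the highest other 4467 (2 of 10 as large). That split set control 1, Sfpq-/- 1 and Sfpq-/- 2 against the rest and so put control 3 and Sfpq-/- 3 together. In the same split the test with own variances called 1 gene. A structure of the samples and the false calls of the F test were therefore not told apart. With own variances the real split gave 582 and the highest other 2. Each other split mixes genotypes within its groups, so changes by genotype enter the residual spread. Low counts there, for genes, probe sets or exon usage, therefore do not show how often a test calls falsely. In Sfpq+/- the F test gave 2 and the highest other split 352 (8 of 10 as large). For gene lists called by camera at the preset correlation the real split gave 9 in Sfpq-/- and the highest other 12 (2 of 10 as large), and in Sfpq+/- 2 and 9 (9 of 10 as large), so the number of lists called does not set the real grouping apart.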

How the results depend on the processing

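Alternatives named as added were chosen after seeing the data. The fall of Sfpq and of long genes in Sfpq-/- kept direction and side of the threshold under every alternative run, with Sfpq between -1.37 and -1.03 and long minus short genes between -0.267 and -0.041. The planned array weights did not converge: they gave Sfpq-/- 1 a weight of 30.1 and Sfpq-/- 3 one of 0.215, so their counts rest mostly on single arrays and are not evidence of more changes. They called 11465 genes in Sfpq-/- and 868 in Sfpq+/- against control, 7198 in Sfpq-/- against Sfpq+/-, 23710 probe sets in Sfpq-/-, exon usage in 7078 and 418 genes, and 4 lists in Sfpq+/-; H1f2, at -0.045 in the planned fit, turned to 0.254. Added gene-by-gene weights, which converged, called 4609, 0 and 3635 genes. For probe sets in Sfpq-/-, no dim filter gave 7161, a trended robust prior 17908, only the groups compared 5837, and leaving out control 3 and Sfpq-/- 3 together (added) 4872; the cause was not tested.

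Exon usage in Sfpq-/- (1282 by F) was 582 with own variances and 2137 without control 3 and Sfpq-/- 3 (both added). In Sfpq+/- (2 by F) it was 157 by Simes, 0 with own variances (added), 8, 1 and 10 genes with probe sets above the 25th percentile, above the 75th percentile and with no dim filter, 10 with only the groups compared and 10 without control 3 and Sfpq-/- 3 (added). The cause of these moves was not tested. Genes changed in Sfpq+/- numbered 1 with the 75th percentile limit. Lists called in Sfpq+/- numbered 1 with that limit, 1 with the median of probe sets and 6 without control 3 and Sfpq-/- 3 (added). The correlation of Sfpq-/- and Sfpq+/- changes (0.187) was 0.213, 0.163 and 0.221 with the 25th percentile, 75th percentile and no dim filter, 0.232 with the median of probe sets, 0.241 with at least 1 kept probe set and 0.224 without control 3 and Sfpq-/- 3; the cause was not tested.

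Leaving out single arrays, against control, gave 1311 to 2453 genes in Sfpq-/- and 0 to 1 in Sfpq+/-, 5594 to 9077 and 0 to 0 probe sets, 864 to 3496 and 1 to 80 genes with exon usage, 7 to 11 and 1 to 4 lists, and a correlation of 0.061 to 0.31. Sfpq-/- against Sfpq+/- gave 1397 to 2267 genes. Sfpq ranged from -1.296 to -1.027 in Sfpq-/- and from -0.019 to 0.216 in Sfpq+/-, and long minus short genes from -0.127 to -0.099 and from 0.023 to 0.051.

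Arrays share replicate numbers across groups, and the deviations of same-numbered arrays correlated unevenly. Arrays numbered 3 deviated together (r = 0.30 to 0.57). Pairs numbered 1 ran from r = -0.06 to 0.28, those numbered 2 from 0.01 to 0.05, and differently numbered pairs from -0.53 to 0.36. A shared source of same-numbered arrays stays open, most for those numbered 3, and the main model holds no block. With the replicate number as a block, 2469 genes were called in Sfpq-/- and 0 in Sfpq+/- against control and 2367 in Sfpq-/- against Sfpq+/-; exon usage in Sfpq+/- was called in 53 genes and 1 list was called there. With the block the Cajal-Retzius list in Sfpq-/- had adjusted p = 0.0511 and the axon guidance list in Sfpq+/- adjusted p = 0.0732.

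Camera calls also ended in other settings. In Sfpq-/- the projection neuron list had adjusted p = 0.257 with the median of probe sets, 0.152 with array weights and 0.0635 with gene-by-gene weights (added). The Cajal-Retzius list had adjusted p = 0.0765, 0.413 and 0.181 in the same settings, and 0.142 without control 3 and Sfpq-/- 3 (added). The S phase list had adjusted p = 0.0534 with the 75th percentile limit and 0.0743 without control 3 and Sfpq-/- 3 (added). In Sfpq+/- the axon guidance list had adjusted p = 0.123 with the 75th percentile limit and 0.32 with the median of probe sets. The cause was not tested.

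Of 2197 refits of the 116 genes named by the rule for Sfpq-/- against control, 1919 kept their call, 185 lost it, 92 gained one and 1 turned direction; all 377 refits of the 20 genes of Sfpq-/- against Sfpq+/- kept it. Of 397 refits of the levels of 21 genes outside the rule, 366 kept their call and 31 lost it, 12 of them for Eomes, 10 for Nxn and 7 for Foxa1. All 160 refits of exon usage by F for 10 genes kept it. Of 171 refits of the 9 lists called in Sfpq-/-, 17 lost the call, and 6 of 38 did for the 2 lists in Sfpq+/-.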

Other observations

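The genes in this paragraph were chosen after their values were seen. The 3 noncoding RNA genes Meg3, Rian and Mirg, which lie with Dlk1 in an imprinted cluster, rose in Sfpq-/- against control cortex. Rian rose by 1.10 (SE 0.17, limma adjusted p = 0.00116), Meg3 by 0.95 (SE 0.10, limma adjusted p = 9.46e-05), Mirg by 0.47 (SE 0.08, limma adjusted p = 0.00297) and Dlk1 by 1.59 (SE 0.17, limma adjusted p = 0.000118). In Sfpq+/- cortex Meg3 differed by 0.13, Rian by -0.03, Mirg by -0.11 and Dlk1 by -0.28, and none passed. The transcription factor genes Dbx1 (1.24), Barhl2 (0.88), Meis1 (1.07) and Tcf7l2 (0.81) and the guidance receptor gene Robo3 (1.01) also rose in Sfpq-/-. Meis1 and Tcf7l2 span over 100 kb and rose, against the direction of most long genes that changed.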
